A study of Rattus norvegicus with 8 samples.

How the data were processed

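RNA was sequenced from neonatal rat cardiomyocytes in 8 libraries, 4 labelled siNC and 4 labelled siECHS1, 48 h after transfection. Per the labels' protocols, libraries were built from 1 µg of total RNA with Illumina's TruSeq RNA kit, which does not mark the strand. The authors deposited FPKM values, 1 column per library and 1 row per Ensembl rat gene, together with gene coordinates, protein matches and Gene Ontology terms. Per the submitters' processing notes, Bowtie 0.12.2 and the genome builds Rnor_6.0 and mm8 were used, without a role for each. The rows carry rat gene identifiers and rat chromosomes, and coordinates are given as the table lists them, without a build named in its header. The counting tool, the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Rows with the same best protein match, and genes that overlap another listed gene, may therefore share reads. Among the genes named, this concerns Echs1, LOC100911186, LOC103694404, LOC103689986, LOC257642, Prdx1, Rrm2 and Mthfd2 by their protein match. By overlap it concerns at least LOC103689986, Emb, Ddit3, Lox, Cacna1h, Gcdh, Yeats2, Bcl2l1, Acot2, Ckm, Myh6, Tagln, Dnajc3, Pdia3, Angptl8, RT1-CE5 and RT1-A2.

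Low values of a gene step in whole reads, so the reads behind each FPKM value, the gene lengths and the library totals were recovered from the steps. Of all values, 100% came out as whole numbers within 0.01 of a read. On simulated data the recovery gave exact read numbers for 99.9% of 3996 genes. The recovered library totals lay between 16953309 and 18237111 reads, and 99.9% of each total fell in listed genes. These reads served to state depth and for an added alternative, and the main test used the FPKM. Within each group, every pair of libraries differed by more than counting noise, with chi-square values per degree of freedom between 2.69 and 6.52, so no library was treated as a repeat of another. All columns of values could be assigned to a library by their names.

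Groups were taken from the labels. Values were transformed to log2(FPKM + 1), genes with a mean of at least 1 FPKM over the 8 libraries were kept (12616 of 21017), and siECHS1 was compared with siNC by limma 3.58.1 in R 4.3.3 with a variance trend on the mean. The test was two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fold changes in FPKM are ratios of group means, and the numbers of genes changed by at least 1.5-fold or 2-fold use the log2(FPKM + 1) scale. Echs1 fell below the filter, so its change is given from the fit without the filter, together with an exact two-sided permutation test over the 70 assignments of 8 libraries to 2 groups of 4. Cochran's Q, used in the closing section for the spread of changes in a marker set, has an exact permutation p: the common shift of the set was taken off and the 8 libraries were regrouped in all 35 splits. It replaced a chi-square p computed first, which 4 libraries a group do not allow, and each explanation kept its outcome. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

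The gene lists, the named-gene rule, the tests and most alternatives were fixed before the data were examined. There were 20 lists and 8 marker sets. The lists covered fatty acid oxidation, branched-chain amino acid degradation, histone acylation, the citric acid cycle, oxidative phosphorylation (nuclear and mitochondrial genes), glycolysis, PPAR alpha and PGC-1 alpha targets, fetal and hypertrophy genes, the sarcomere, calcium handling and ion channels. They also covered ATF4 targets, the unfolded protein and heat shock response, the NRF2 response, p53 and apoptosis, the cell cycle, the interferon response, NF-kB and cytokines, the extracellular matrix, and cholesterol and fatty acid synthesis. The marker sets were those of cardiomyocytes, fibroblasts, smooth muscle cells and pericytes, endothelial cells, macrophages and leukocytes, erythroid cells, epicardial and mesothelial cells, and Schwann and neural cells. Several genes stand in both a list and a marker set, among them Myh6 and Myl7 (sarcomere and cardiomyocyte) and Col1a1 and Postn (matrix and fibroblast). Echs1 was left out of every list, and a symbol that matched no row was not analysed here. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 28 sets, with an estimated correlation and fry as alternatives. Gene Ontology terms with 10 to 500 tested genes were tested by a one-sided Fisher's exact test among risen and fallen genes, against tested genes with a term of the same ontology, adjusted within each direction and ontology. Some term cells of the table (1121 rows for biological process) were blanked in the copy used here, and those genes count as having no such term.

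The genes named are Echs1, the 10 largest rises and the 10 largest falls among genes past the threshold with a symbol and groups that do not overlap, and up to 3 members of each list by smallest adjusted p. In a list with no member past the threshold, up to 2 of the most abundant members are given as values. Up to 3 risen genes are named for an enriched term, by smallest adjusted p. Some genes that these rules pick are not reported here by name, though they count in the totals of lists and terms. LOC100911186 was named because of its protein match to Echs1, after its values were seen, and genes named beyond the rule are marked where they appear.

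The comparison was tested on simulated data made for the real genes from their own means and the library totals, with 200 seeded changes among 12624 genes tested. All genes were given 1 dispersion, 0.00181, the median of well-covered genes, so recovery may be overstated for genes with more spread. For siECHS1 against siNC so simulated, 54% of the seeded changes of 1.2-fold, 94% of those of 1.5-fold, 98% of those of 2-fold and 100% of those of 3-fold were recovered, and 4.10% of the calls were false. The alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, median-of-ratios, quantile and TPM scaling, a replicate block, robust and trend-free variance models, library quality weights, a 1.5-fold threshold, an adjusted p of 0.01, summed rows of equal symbol, another enrichment background and each library left out in turn. Limma-voom on the recovered reads, the sum of Echs1 and LOC100911186, the ratio of mean FPKM without a pseudocount and a correction for gene length were added after seeing the data.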

Results

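Transcript levels were measured by RNA sequencing in neonatal rat cardiomyocytes, heart muscle cells isolated from newborn Sprague-Dawley rats, 48 h after transfection with a small interfering RNA. The cells received either siECHS1, directed against Echs1, or siNC, the control duplex, and each group held 4 libraries. Echs1 encodes the short-chain enoyl-CoA hydratase of the mitochondrial matrix, which hydrates enoyl-CoA esters in fatty acid beta-oxidation and in the breakdown of valine. The comparison of siECHS1 with siNC addressed which transcripts of the cardiomyocytes differ when Echs1 transcripts are lowered. Library totals lay between 16953309 and 18237111 reads, and the table listed 21017 genes in FPKM (fragments per kilobase of gene, scaled to the library total). Values below are mean FPKM ± SD over the 4 libraries of a group. Fold changes on the log2 scale refer to log2(FPKM + 1), which understates the change of low genes. The labels do not say that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

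The targeted transcript was lower in all 4 siECHS1 libraries than in any siNC library. The row named Echs1 (ENSRNOG00000047565, chromosome 1, 141821916 to 141830764, plus strand) fell from 1.33 ± 0.244 to 0.516 ± 0.112 FPKM, which left 38.8% of the control level. A further row, LOC100911186 (ENSRNOG00000018522, chromosome 1, 212570195 to 212579057, minus strand), has the same rat enoyl-CoA hydratase as its best protein match. It fell from 6.61 ± 0.782 to 3.38 ± 0.385 FPKM, or 51.1% of control. Summed, the 2 rows gave 7.94 ± 0.559 FPKM in siNC and 3.90 ± 0.329 in siECHS1, a level 50.9% lower. The Echs1 row rested on 138 reads in siNC and 55 in siECHS1, and LOC100911186 on 690 and 363. How the authors assigned reads that match both loci is not given in the sources used here, so the split between the rows is uncertain. If such reads were discarded, the summed level and the size of its fall are uncertain too. On the log2(FPKM + 1) scale Echs1 changed by -0.62 (SE 0.09), and the exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 libraries allow. Its mean of 0.922 FPKM lay below the filter for the comparison of all genes, and without that filter limma gave an adjusted p of 0.00374. For LOC100911186 the change was -0.80 (SE 0.09, limma adjusted p = 0.000272).

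**Figure D1:**
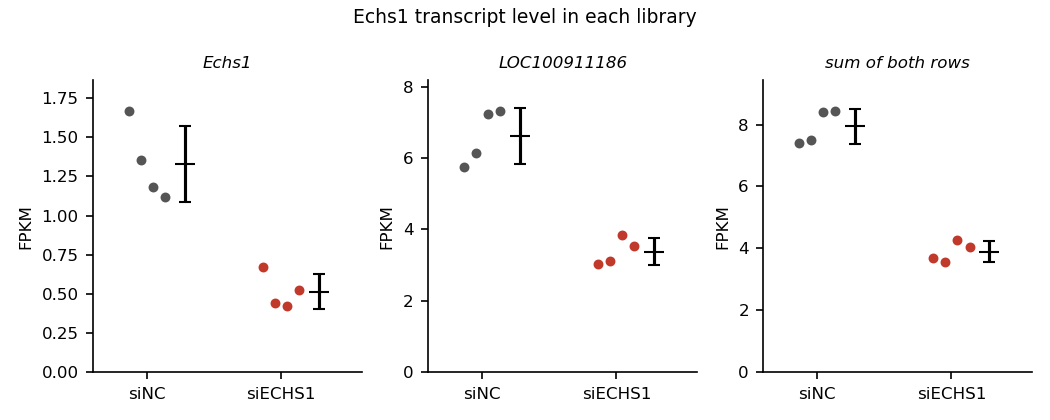
Transcript level in FPKM (y axis) of the row Echs1, of LOC100911186 and of their sum in the siNC and siECHS1 groups (x axis). Each point is 1 of the 4 libraries of a group, and the bars are the mean and SD. Every siECHS1 library lay below every siNC library in each panel, with sums of 7.94 FPKM in siNC and 3.90 in siECHS1.

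The knockdown was accompanied by many small changes. Among the transcripts that rose were those of the chaperone Hspa5, the ATF4 target Gdf15, the collagen Col1a1, the lysosomal protease Lgmn and the hypertrophy marker Nppb, and among those that fell were the citric acid cycle gene Dlst, the light chain Myl7 and the calcium pump Atp2a2. Among 12616 genes with a mean of at least 1 FPKM, 2655 (21.0%) passed an adjusted p of 0.05, of which 1114 rose and 1541 fell. The median change was 0.26 on the log2 scale among the risen genes and 0.24 in size among the fallen. At least 1.5-fold changes numbered 64 upward and 46 downward, and at least 2-fold changes 7 in each direction. The first principal component held 36.9% of the variance and placed the 4 siNC libraries apart from the 4 siECHS1 libraries. The 4 values of a group did not overlap those of the other in 25.2% of the tested genes, against 2.86% by chance. With median-of-ratios scaling in place of the FPKM as deposited, 1288 genes rose and 1242 fell, so which direction held more genes depended on the scaling.

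Genes were ranked only if they passed the threshold, had a symbol and had groups that did not overlap, so larger changes of other genes are not listed. Among the ranked genes, Lgmn (ENSRNOG00000007089, chromosome 6, 126282233 to 126320726) had the largest rise on the log2(FPKM + 1) scale. Lgmn encodes the lysosomal cysteine protease legumain. It went from 71.1 ± 1.61 to 181 ± 5.33 FPKM, 2.55-fold, with a log2 change of 1.34 (SE 0.03, adjusted p = 1.18e-08). By the ratio of mean FPKM, RGD1560112 rose more (2.98-fold), and the low gene Tmem59l slightly more. The other 9 of the 10 largest rises of ranked genes on the log2 scale were RGD1560112, Emb, Hpx, Tmem59l, LOC103694404, Ccdc71l, Akr1b10, Impact and Lcn2. Among the more abundant of these, Lcn2, the iron-siderophore-binding lipocalin 2, rose from 465 ± 21.0 to 877 ± 47.6 FPKM, and Akr1b10, an aldo-keto reductase, rose from 18.7 ± 1.38 to 36.3 ± 1.34. Impact, a regulator of the eIF2 kinase GCN2, rose from 9.61 ± 1.2 to 19 ± 1.35. The hemopexin gene Hpx rose from 4.15 ± 0.165 to 9.32 ± 0.356, and the embigin gene Emb from 8.95 ± 0.405 to 19.9 ± 1.82. RGD1560112, Tmem59l, LOC103694404 and Ccdc71l were low, at 1.90, 1.66, 1.82 and 1.23 FPKM in siNC and 5.66, 4.24, 4.37 and 3.12 in siECHS1. LOC103694404 shares its best protein match, a ribosomal protein, with 2 other rows, so its level is uncertain.

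Among genes ranked by the same rule, the largest fall on the log2(FPKM + 1) scale was that of LOC103689986 (chromosome 1). It went from 8.47 ± 0.641 to 2.16 ± 0.291 FPKM, 3.92-fold, with a log2 change of -1.59 (SE 0.08, adjusted p = 3.33e-06). Its best protein match is shared with 1 other row and it overlaps LOC100361913, so its level is uncertain too. Ankrd13a, which encodes an ankyrin repeat protein, fell 1.99-fold from 51.7 ± 1.97 to 25.9 ± 2.03 FPKM. The nociceptin precursor Pnoc fell from 6.43 ± 0.599 to 2.12 ± 0.360, and the metalloproteinase Mmp12 from 11.8 ± 0.917 to 6.31 ± 2.2. The chemokine Ccl17 fell from 2.24 ± 0.444 to 0.543 ± 0.295, 4.12-fold, more than LOC103689986 by this ratio. In siECHS1 the Ccl17 libraries lay between 0.389 and 0.985 FPKM, a level that rests on few reads, so its ratio is uncertain. The short row Mir675 fell from 120 ± 18.7 to 52.4 ± 5.73 FPKM. LOC103690354 fell 2.35-fold and LOC103690015 2.37-fold. The 2 rows named LOC257642, which share their protein match, each fell 2.02-fold.

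Many genes of the stress response lists rose. Of the 26 tested ATF4 targets of the integrated stress response, which restores amino acid supply and slows translation, 10 rose and 0 fell by limma over all genes tested, and 13 and 0 adjusted over the list alone (1 lower at an unadjusted p under 0.05). Gdf15, a secreted stress cytokine, rose from 48.0 ± 3.07 to 67.6 ± 5.46 FPKM, Ddit3, the transcription factor CHOP, from 66.5 ± 2.79 to 87.4 ± 5.20, and the amino acid transporter subunit Slc3a2 from 130.1 ± 3.58 to 164.5 ± 5.09. Camera gave this list an adjusted p of 3.09e-05, and adjusted p = 0.358 with an estimated correlation. In the unfolded protein and heat shock list 9 of 22 tested genes rose and 1 fell, and 13 and 2 adjusted over the list alone. The endoplasmic reticulum chaperones Hspa5 (BiP) and Hsp90b1 (GRP94) rose from 249.8 ± 5.79 to 355.6 ± 2.38 and from 127.8 ± 8.79 to 171.8 ± 7.31 FPKM, and calreticulin, Calr, from 923 ± 15.7 to 1075 ± 23.8. The member that fell was the cytosolic co-chaperone Dnajb1 (log2 change -0.14), and the heat shock genes Hspb1, Hspd1, Hspe1 and Hsph1 did not pass the test; these 5 were named after their values were seen. Under quantile normalization Hspb1 passed (log2 change 0.08, adjusted p = 0.0196). The camera adjusted p was 0.000366, and adjusted p = 0.101 with an estimated correlation. Among all annotated terms, endoplasmic reticulum lumen was the most enriched in the risen genes by its p, with 28 of 79 members against 7.28 expected (Fisher's exact test, adjusted p = 5.16e-08). It included Kdelc2 (26.5 ± 1.26 to 38.4 ± 2.16 FPKM) and Dnajc3 (33.5 ± 0.754 to 43.0 ± 1.24). Fisher's exact test takes genes as independent, so genes that move together can make its p too small, here and for the terms below.

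Of 19 tested genes of the NRF2 antioxidant response, 6 rose and 1 fell, and 7 and 2 adjusted over the list alone. The peroxiredoxin Prdx1 rose from 320.4 ± 9.78 to 381 ± 15.3 FPKM and Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, from 21.7 ± 0.526 to 25.5 ± 0.794. The glutathione transferase Gsta4 was the member that fell, from 65.1 ± 1.65 to 52.7 ± 1.73. The camera adjusted p was 0.0271, and adjusted p = 0.358 with an estimated correlation. This call ended when genes under 5 FPKM were left out (adjusted p = 0.0627) and without siNC replicate 1 (adjusted p = 0.0613), within a range from 0.0128 to 0.0627 over the alternatives at the preset correlation.

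Some transcripts of mitochondrial energy metabolism fell by small amounts, and of these lists only the citric acid cycle was called by camera. Of 19 tested genes of the citric acid cycle and the pyruvate dehydrogenase complex, 10 fell and 1 rose, and 11 and 1 adjusted over the list alone. Dlst, a subunit of the 2-oxoglutarate dehydrogenase complex, fell from 104.5 ± 0.773 to 89.0 ± 0.618 FPKM. Sdhd, a membrane anchor of succinate dehydrogenase, fell from 190.7 ± 4.49 to 162.4 ± 5.97, and the isocitrate dehydrogenase subunit Idh3g from 141 ± 5.29 to 121.5 ± 5.39. The camera adjusted p for this list was 0.00285, and adjusted p = 0.618 with an estimated correlation. Among nuclear genes of oxidative phosphorylation 7 of 37 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.125). The complex I subunits Ndufa10 and Ndufv1 fell 1.30-fold and 1.2-fold, and the complex III core protein Uqcrc1 fell from 294.5 ± 17.9 to 238 ± 10.3 FPKM. Of 12 mitochondrially encoded genes, Mt-co1 fell 1.14-fold and 11 did not pass, also over the list alone (camera adjusted p = 0.275). The call for Mt-co1 was lost without siNC replicate 2 (adjusted p = 0.0747) or 4 (0.0537) and without siECHS1 replicate 1 (0.0637), 2 (0.0608) or 3 (0.0518). It was also lost without the filter on low values (0.457) and under quantile normalization, where the change was 0. That 0 was fixed by construction, because the method gives a gene of equal rank in every library the same value. It therefore says nothing about Mt-co1. Mitochondrial transcripts took 5.73% ± 0.240 of the reads in siNC and 5.16% ± 0.174 in siECHS1.

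In fatty acid oxidation, the pathway in which Echs1 itself acts, 6 of 23 tested genes fell and 1 rose, and 10 and 3 adjusted over the list alone (camera adjusted p = 0.122). Eci1, an enoyl-CoA isomerase, fell from 73.4 ± 3.84 to 57.8 ± 1.80 FPKM, Cpt1a, a carnitine palmitoyltransferase of the outer mitochondrial membrane, from 48.1 ± 1.14 to 41.5 ± 1.19, and the carnitine carrier Slc25a20 from 56.9 ± 1.23 to 50.5 ± 1.59. Branched-chain amino acid degradation moved both ways, with 3 of 24 genes up and 6 down, and 3 and 7 adjusted over the list alone (camera adjusted p = 0.275). Dbt, the transacylase core of the branched-chain keto acid dehydrogenase, rose from 6.45 ± 0.489 to 9.70 ± 0.449 FPKM. The aminotransferase Bcat1 rose 1.26-fold, while the mitochondrial aminotransferase Bcat2 fell 1.18-fold. Of 28 writers, erasers and readers of histone acylation and genes of acyl-CoA supply, 2 rose and 7 fell, and 3 and 10 adjusted over the list alone (camera adjusted p = 0.122). The acyl-lysine readers Mllt1 and Yeats2 fell 1.2-fold and 1.16-fold, and Gcdh, which makes crotonyl-CoA from glutaryl-CoA, fell from 34.2 ± 0.470 to 29.8 ± 0.725 FPKM.

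Lists for other branches of metabolism were split. In glycolysis 3 of 24 genes rose and 5 fell, and 4 and 7 adjusted over the list alone (camera adjusted p = 0.889). The muscle isoforms Eno3 and Pgam2 fell 1.58-fold and 1.34-fold, while the liver-type phosphofructokinase Pfkl rose 1.19-fold. Of 16 tested PPAR alpha and PGC-1 alpha targets and regulators, 2 rose and 1 fell, and 3 and 4 adjusted over the list alone (camera adjusted p = 0.887). Lipoprotein lipase, Lpl, rose from 115.6 ± 3.79 to 133.3 ± 2.05 FPKM and its inhibitor Angptl4 from 15.9 ± 2.43 to 20.9 ± 1.29, and the thioesterase Acot2 fell 1.21-fold. Among 22 genes of cholesterol and fatty acid synthesis 2 rose and 5 fell, and 3 and 5 adjusted over the list alone (camera adjusted p = 0.358). The sterol reductase Dhcr7 fell 1.43-fold.

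Genes of the cardiac program moved in both directions. Nppb, which encodes the hypertrophy marker brain natriuretic peptide, rose 1.52-fold from 499.7 ± 17.4 to 761 ± 69.8 FPKM, and Xirp1, an actin-binding protein of the intercalated disc, rose from 41.5 ± 2.21 to 54.5 ± 2.2. The transcription factor gene Gata6 fell from 32.6 ± 0.509 to 27.7 ± 0.826. In the list of fetal genes, hypertrophy markers and their regulators, 5 of 25 rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.812). Nppa and Myh7 were among those that rose (log2 changes 0.29 and 0.24), and Acta1, Gata4 and Srf among those that fell (-0.21, -0.23 and -0.18); these 5 were chosen after their values were seen. Of 25 sarcomere genes 4 rose and 8 fell, and 4 and 9 adjusted over the list alone (camera adjusted p = 0.501). The atrial light chain Myl7 fell from 73.6 ± 3.00 to 45.3 ± 3.02 FPKM, 1.62-fold, and the Z-disc gene Ldb3 from 101.3 ± 2.91 to 81.9 ± 3.66. Myl9, a regulatory light chain of smooth muscle and non-muscle myosin that stood in this list, fell from 941 ± 36.0 to 663.7 ± 34.4. Of 27 calcium handling and ion channel genes 7 fell and 0 rose by limma, with the same counts adjusted over the list alone and at an unadjusted p under 0.05 (camera adjusted p = 0.322). The sarcoplasmic reticulum calcium pump Atp2a2 fell from 611 ± 17.5 to 504.5 ± 14.8 FPKM, the T-type calcium channel Cacna1h 1.37-fold and the potassium channel Kcnh2 1.33-fold. Intercalated disc, the junction between heart muscle cells, was enriched among the risen genes, with 12 of 38 members against 3.50 expected (Fisher's exact test, adjusted p = 0.00420). Beside Xirp1, these included Hamp, which encodes hepcidin (11.8 ± 1.21 to 16.9 ± 1.66 FPKM).

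**Figure D2:**
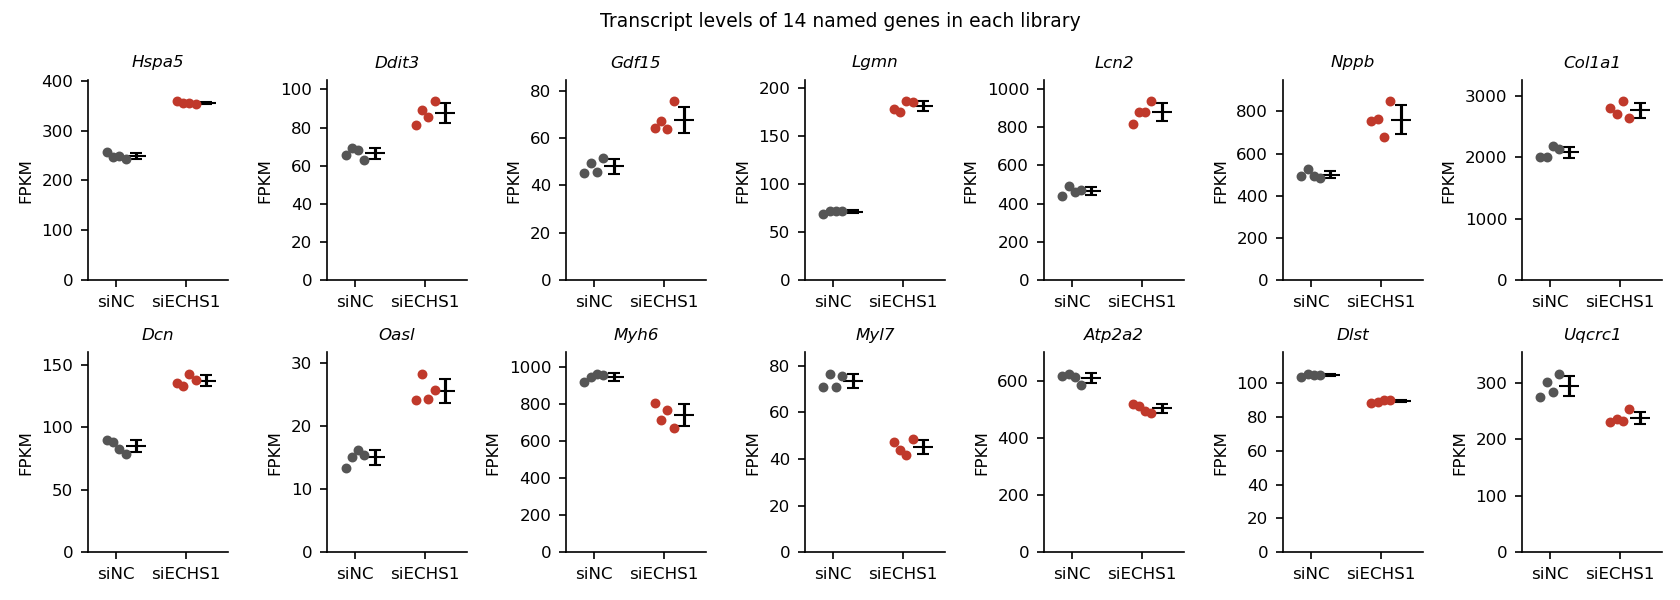
Transcript level in FPKM (y axes, each from 0) of 14 named genes in the siNC and siECHS1 groups (x axes). Each point is 1 of the 4 libraries of a group, and the bars are the mean and SD. The siECHS1 libraries lay above the siNC libraries for Hspa5, Ddit3, Gdf15, Lgmn, Lcn2, Nppb, Col1a1, Dcn and Oasl, and below them for Myh6, Myl7, Atp2a2, Dlst and Uqcrc1.

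Several extracellular matrix transcripts rose. Col1a1, the alpha 1 chain of type I collagen, rose from 2087 ± 90.9 to 2768 ± 117 FPKM, the collagen cross-linking enzyme Lox from 59.7 ± 2.37 to 84.2 ± 6.85, and the matricellular protein gene Postn from 129.2 ± 6.19 to 166.7 ± 4.91. Of 29 genes of the extracellular matrix and TGF-beta response list, 8 rose and 2 fell, and 12 and 2 adjusted over the list alone. The camera adjusted p was 0.00109, and adjusted p = 0.603 with an estimated correlation. Collagen trimer was enriched among the risen genes, with 13 of 35 members against 3.23 expected (Fisher's exact test, adjusted p = 0.000657), among them Col5a2 (162.0 ± 6.09 to 201.4 ± 7.34 FPKM) and Col14a1 (58.3 ± 1.87 to 76.8 ± 5.73). Cell adhesion was also enriched, with 41 of 175 members against 15.8 expected (adjusted p = 6.50e-06). The hyaluronan receptor Cd44 rose 1.61-fold from 30.4 ± 1.23 to 48.9 ± 1.28 FPKM.

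In no marker set of the cell types a neonatal heart culture can hold did every tested member change. Fry's test of a common direction, which compares a set with no other genes, passed the cardiomyocyte set downward (adjusted p = 0.00664). It also passed the fibroblast set upward (0.00282) and the erythroid set downward (0.0329), and none of the other marker sets. Of 10 cardiomyocyte markers 5 fell, among them Myl7, Ckm (70.4 ± 5.40 to 51.3 ± 2.87 FPKM) and Myh6 (948 ± 19.3 to 741 ± 59.0), and 1 rose (camera adjusted p = 0.194). Of 9 fibroblast markers 4 rose and 1 fell, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.156). Decorin, Dcn, rose from 85.0 ± 5 to 137.3 ± 4.29 FPKM, together with Postn and Col1a1, which also stand in the matrix list. Lum, chosen after its value was seen, fell (log2 change -0.19). The smooth muscle and pericyte set had 1 rise, Acta2 (1.11-fold), and 1 fall, Tagln (1.25-fold), among 8 (camera adjusted p = 0.887). Among 9 endothelial markers Esam fell 1.26-fold and 0 rose (camera adjusted p = 0.795). Of 5 macrophage and leukocyte markers Cd68 rose 1.27-fold and Csf1r fell 1.32-fold (camera adjusted p = 0.795), and of 5 epicardial and mesothelial markers Upk1b rose 1.35-fold and Wt1 fell 1.35-fold (camera adjusted p = 0.737). Acta2 and Wt1 lost their calls without siNC replicate 2 (adjusted p = 0.0614 and 0.0663), 3 (0.0582 and 0.0631) or 4 (0.0507 and 0.0729) and without siECHS1 replicate 1 (0.0616 and 0.0632). Wt1 also did so without siECHS1 replicate 2 (0.0747) or 3 (0.0519). Without the filter on low values neither passed (0.106 and 0.0591), and under quantile normalization Acta2 did not (0.0549). The epicardial set had 1 rise and 2 falls adjusted over the list alone, and the remaining marker sets kept their counts. Of 3 erythroid markers 0 passed limma's test, with 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.501), with Ahsp at 1.67 FPKM in either group and Hba-a2 at 1.91 and 1.13. Hba-a2 passed without siECHS1 replicate 3 (log2 change -0.62, adjusted p = 0.0435). Of 3 Schwann and neural markers 0 passed, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.737), with Tubb3 at 9.02 and 10.2 FPKM and S100b at 7.15 and 6.77. Tubb3 passed without siECHS1 replicate 1 (log2 change 0.24, adjusted p = 0.0147).

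Immune genes moved in both directions. Among 24 tested genes of the interferon response and innate immune sensing 3 rose and 12 fell, and 4 and 12 adjusted over the list alone (camera adjusted p = 0.127). Oasl, an oligoadenylate synthetase-like protein, and Ifit3 rose from 15.1 ± 1.23 to 25.7 ± 1.91 and from 17 ± 1.17 to 28.1 ± 2.65 FPKM. Cxcl10 was the further member that rose (log2 change 0.61), and Stat2 (-0.40), Usp18 (-0.59) and Mx2 (-0.47) were among those that fell; these 4 were chosen after their values were seen. In the NF-kB and inflammatory cytokine list 5 of 18 rose and 3 fell, and 5 and 4 adjusted over the list alone (camera adjusted p = 0.737). Lcn2 led this list, the chemokine Ccl7 rose from 48.3 ± 4.27 to 76.1 ± 3.98 FPKM, and the mitochondrial superoxide dismutase Sod2 rose 1.15-fold. Chemokine activity was enriched among the risen genes, with 9 of 25 members against 2.31 expected (Fisher's exact test, adjusted p = 0.0211), including Ccl6 (1.38 ± 0.143 to 3.34 ± 0.288 FPKM) and Cx3cl1 (57.5 ± 2.25 to 76.1 ± 3.33).

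The classical pathway of complement activation had 6 risen genes of 11 against 0.990 expected (Fisher's exact test, adjusted p = 0.0189). The proteases C1s and C1r rose 1.39-fold and 1.22-fold, and their inhibitor Serping1 rose from 266.4 ± 9.86 to 370.6 ± 27.7 FPKM. The MHC class I protein complex had 8 of 21 against 1.94 (adjusted p = 0.0110), among them B2m, the invariant light chain (1036 ± 18.4 to 1332 ± 48.8 FPKM). The class I heavy chain genes RT1-A2 and RT1-CE5 rose 1.49-fold and 1.34-fold, but they overlap other class I genes and their levels are uncertain. Lysosome had 35 of 178 against 16.4 (adjusted p = 0.000935), with Lgmn, the protease cathepsin L (Ctsl, 429.5 ± 10.4 to 593 ± 18.5 FPKM) and the amidase Naaa (2.26 ± 0.162 to 4.56 ± 0.388).

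A minority of the cell cycle genes rose. Of 28 tested genes of the cell cycle and DNA replication 5 rose and 0 fell by limma, and 4 and 0 adjusted over the list alone (10 higher and 0 lower at an unadjusted p under 0.05). Cyclin D1, Ccnd1, rose from 63.8 ± 2.02 to 78.4 ± 2.56 FPKM, the replication clamp Pcna 1.10-fold and the ribonucleotide reductase subunit Rrm2 1.16-fold. The camera adjusted p was 0.00156, and adjusted p = 0.358 with an estimated correlation. Pcna no longer passed without siNC replicate 3 (adjusted p = 0.0596) or 4 (0.0547) or siECHS1 replicate 1 (0.0532) or 2 (0.0634). Rrm2 no longer passed without siNC replicate 4 (0.0698) or siECHS1 replicate 2 (0.0756) or 3 (0.0678), or without the filter on low values (0.0575). In the p53 and apoptosis list 3 of 22 genes rose and 6 fell, and 4 and 7 adjusted over the list alone (camera adjusted p = 0.887). The p53 target Zmat3 rose from 16.0 ± 1.11 to 22.3 ± 2.61 FPKM, whereas Sesn1 fell 1.2-fold and the survival gene Bcl2l1 1.17-fold.

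**Figure D3:**
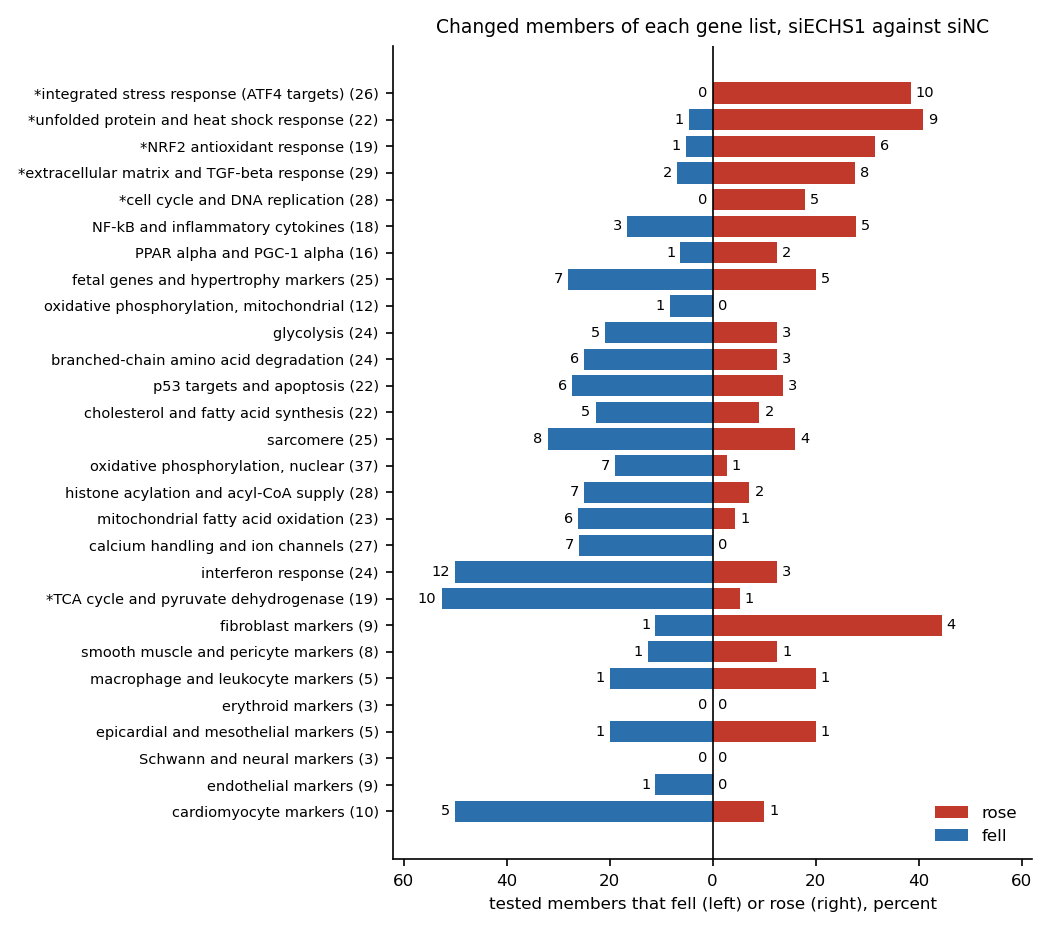
Share of the tested members of each gene list or marker set (y axis, number tested in brackets) that rose (right) or fell (left) in siECHS1, in percent (x axis), with the number of genes at each bar. An asterisk marks the 6 sets called by camera: 5 upward, from the ATF4 targets (10 of 26 rose) to the cell cycle (5 of 28), and 1 downward, the citric acid cycle (10 of 19 fell).

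Of the 28 lists and marker sets, camera with a preset correlation of 0.01 called 6, and 0 of these calls held with an estimated correlation, where 2 sets had an unadjusted p under 0.05. Of the 35 splits of the 8 libraries into 4 and 4, 8 gave at least 6 called sets, so the number of camera calls was not beyond what regrouping the libraries gives. Most of the other splits that reached 6 kept 3 libraries of a group together, and with them part of the group difference. They are therefore not a clean reference for chance. Fry passed 12 sets in its test of a common direction and 25 in its test of change in either direction, which compare a set with no other genes. In 3 sets the median differed in sign from the mean and the test: the p53 list (median 0.000099, mean -0.0090, test downward), the NF-kB list (median -0.06, mean 0.06, test upward) and the fibroblast markers (median -0.02, mean 0.12, test upward). Terms numbered 37 among the risen genes. Among the fallen genes 0 of 1742 terms passed Fisher's exact test, with 89 at an unadjusted p under 0.05, and the tricarboxylic acid cycle had 11 of 26 members (adjusted p = 0.134).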

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

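In 13 of 278 groups of 4 libraries, the highest or lowest library stood apart from the other 3 by more than Dixon's test allows at the 95% level. The groups covered the named genes, the summed Echs1 rows, the library totals and the mitochondrial share of reads. Chance alone sets about 5% of groups apart, so this number is close to what chance gives. No explanation was tested for these values.

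Among the control libraries, siNC replicate 1 was low for Lgmn (68.7 FPKM, others from 71.6 to 72.1) and Cpt1a (46.4, others from 48.6 to 48.8), and siNC replicate 2 was high for Sod2 (100.5, others from 95.3 to 95.9). In siNC replicate 3, Col3a1 was high (534 FPKM, others from 507.1 to 507.5) and Lum low (23.8, others from 26.6 to 27.1). In siNC replicate 4, C1s was low (104.9 FPKM, others from 114 to 115) and Gata4 high (144 FPKM, others from 131 to 132.5).

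Among the knockdown libraries, siECHS1 replicate 2 was low for LOC103689986 (1.73 FPKM, others from 2.29 to 2.34). In siECHS1 replicate 3, Dhcr7 was high (14.2 FPKM, others from 12.1 to 12.2) and Naaa low (3.98, others from 4.69 to 4.81). In siECHS1 replicate 4, Ccl17 was high (0.985 FPKM, others from 0.389 to 0.405), Slc25a20 high (52.8, others from 49.4 to 50) and Gclc low (24.3, others from 25.8 to 26.0). At the level of Ccl17 values step in whole reads, so its flag may rest on few reads.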

How the results depend on the processing

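The runs of limma-voom on recovered reads, of the summed Echs1 rows, of the ratio without a pseudocount and of the length correction were chosen after seeing the data. A quasi-likelihood test on a table of counts was not run, since the values used here are FPKM. The number of changed genes stayed within 1.5 times of 2655 under every other scaling, pseudocount, filter and variance model run. A threshold of 1.5-fold gave 110 genes (64 up, 46 down) and an adjusted p of 0.01 gave 1242 (551 up, 691 down), because fewer genes meet a stricter threshold. Leaving out a library gave 1894 to 2671 genes, 792 to 1182 of them up and 1102 to 1553 down. Limma-voom on the recovered reads, all of whose values came out whole, called 2948 genes (1249 up, 1699 down) and shared 2543 with the 2655, of which 0 had the opposite sign. The share of changed genes that rose, 42.0% as deposited, was 50.9% with median-of-ratios, 47.1% with quantile and 45.9% with TPM scaling, and 48.2% of 2812 genes with the length correction. That length correction also rescales the libraries.

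Echs1 stayed lower and past the threshold in each setting in which it was tested, with -0.66 to -0.55 when a library was left out and -0.87 for the summed rows. The ratio of mean FPKM without a pseudocount gave -1.37, larger in size because a pseudocount of 1 shrinks the change of a gene near 1 FPKM. The 6 called lists became 0 with an estimated correlation, for which the cause was not tested. For the unfolded protein and heat shock list the estimated correlation was -0.00485, under the preset 0.01. Its unadjusted camera p still went from 2.62e-05 to 0.00359, which argues against a higher correlation between genes as what ended this call. The called lists became 12 with fry for direction and 25 with fry for change in either direction, since fry does not compare a list with other genes. Leaving out a library gave 6 to 8 called lists and 26 to 49 enriched terms (26 to 47 among risen genes). Enriched terms among fallen genes were 0 as reported, 2 without a filter, 2 with quantile normalization, 1 with quality weights, and 0 to 2 when a library was left out (1 without siNC replicate 4 and 2 without siECHS1 replicate 4); the cause was not tested.

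Reversals concerned results that were not called. For lists the value here is the mean log2 fold change minus that of the other genes, so it can be positive where the mean is negative. That of the p53 list was 0.00072 as reported, -0.0011 without a filter, -0.0062 from 5 FPKM, and between -0.0058 and -0.00041 in the 5 runs without siNC replicate 2 (-0.0040) or 4 (-0.0030) or without siECHS1 replicate 1, 2 (-0.0022) or 3. The Schwann markers went from 0.063 to -0.014 without a filter, the macrophage markers from -0.080 to 0.0096 from 5 FPKM, the fetal gene list from 0.0078 to -0.0023 without siECHS1 replicate 1 and the PPAR list from -0.019 to 0.0064 without siECHS1 replicate 4. Ahsp reversed from -0.04 to 0.042 with quality weights and to 0.079 and 0.062 without siECHS1 replicate 3 and 4, and Hspb1 from 0.026 to -0.0036 without siNC replicate 1 and -0.0066 without siECHS1 replicate 4. The other ends of the ranges over left-out libraries were 0.0113 for the p53 list, 0.0143 for the fetal gene list, -0.0308 for the PPAR list, -0.153 for Ahsp and 0.0514 for Hspb1. The cause was not tested. Of 2686 values of 135 named genes under 20 settings, 2680 kept their direction, 1 was 0 by construction (Mt-co1 under quantile normalization), 5 reversed, 28 no longer passed and 5 newly passed. The value fixed at 0 counts among the 28. The 28 belonged to Mt-co1, Wt1, Acta2, Pcna and Rrm2, and the 5 that newly passed to Hba-a2 (2 settings), Hspb1, Hspd1 and Tubb3.

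The fatty acid oxidation and histone acylation lists passed camera without a filter (adjusted p = 0.0235 and 0.0232), and nuclear oxidative phosphorylation did so with quantile normalization (0.0248) and quality weights (0.0168). Fatty acid oxidation also passed without siNC replicate 1 or siECHS1 replicate 4 (0.0486 and 0.0330), as did nuclear oxidative phosphorylation (0.0434 and 0.000951). Deviations of same-numbered libraries from their group means correlated at 0.17, -0.05, 0.01 and 0.07, so the numbers were not taken to pair the libraries. The second principal component, with 13.7% of the variance, nevertheless fell in the order of the replicate numbers in both groups. It went from 10.7 to -6.88 in siNC and from 7.39 to -10.3 in siECHS1. A difference that follows the replicate number, such as one of batch, is therefore not excluded, and its cause was not tested. With the replicate number as a block 2952 genes passed (1283 up, 1669 down), Echs1 stayed at -0.62, and the mitochondrially encoded list passed camera (adjusted p = 0.0381), as did Hba-a2 (-0.47, adjusted p = 0.0494) and Hspd1 (0.11, adjusted p = 0.0336) limma's test. Depth limits the low genes: Echs1 rested on 11 to 45 reads a library.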

Other observations

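The tests of cell shares, of scaling, of gene length and of the interferon genes below were chosen after the results were seen.

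Several further terms were enriched among the genes that rose in siECHS1. Protein disulfide isomerase activity, the formation of disulfide bonds in secreted proteins, had 7 of 16 members among the risen genes against 1.48 expected (Fisher's exact test, adjusted p = 0.0214). Pdia3 rose from 438.7 ± 14.4 to 519.8 ± 9.95 FPKM, P4hb from 631.5 ± 16.4 to 738 ± 22.3 and Tmx3 from 19.5 ± 1.22 to 25.6 ± 1.6. One-carbon metabolism had 8 of 23 members against 2.07 (adjusted p = 0.0464). Its genes included the mitochondrial folate enzymes Mthfd2 (33.5 ± 0.961 to 38.8 ± 1.39) and Aldh1l2 (5.22 ± 0.309 to 6.53 ± 0.435), which are also ATF4 targets, and the carbonic anhydrase-related gene Car8 (1.15-fold). Basement membrane had 17 of 71 against 6.54 (adjusted p = 0.00652), with the laminin chain Lamb3 (28.2 ± 0.853 to 37.5 ± 0.561) and the thrombospondin Thbs2 (1.34-fold). Among structural constituents of the matrix, 12 of 32 rose against 2.96 (adjusted p = 0.00202), with the matrix Gla protein gene Mgp going from 1286 ± 35.4 to 1755 ± 93.0.

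Terms for secreted inhibitors and hormones were enriched as well. Serine-type endopeptidase inhibitor activity had 11 of 34 members against 3.14 (adjusted p = 0.0164), with Slpi, the secretory leukocyte protease inhibitor, rising from 21.7 ± 2.26 to 38.0 ± 4.57 FPKM and the amyloid precursor-like gene Aplp2 1.19-fold. Hormone activity had 6 of 14 against 1.29 (adjusted p = 0.0422), with Nppb, Angptl8 (2.62 ± 0.401 to 5.22 ± 0.889) and cholecystokinin, Cck, which stayed low (0.667 ± 0.020 to 1.6 ± 0.103). Carbohydrate binding had 20 of 95 against 8.78 (adjusted p = 0.0214), among them the secreted lectin Reg3b (171 ± 10.5 to 276 ± 21.4) and Cd24 (1.27-fold).

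All 35 splits of the 8 libraries into 4 and 4 were run through the same tests. The real split gave 2655 changed genes and the highest of the others 2, and 1 of the 35 splits, the real one, reached 2655. A random regrouping of these libraries is thus an unlikely source of the number of changed genes, at the smallest share that 35 splits allow. The other splits mix both groups, so a difference between the groups widens their spread and keeps their counts low. The splits cannot tell an effect of the siRNA from another difference between the groups, such as one of culture or batch. For enriched terms the real split gave 37 and the highest of the others 0, again 1 of 35 splits, but with at most 2 changed genes the other splits left no room for enriched terms, so this is no separate evidence against chance. For gene lists called by camera the real split gave 6 and the highest of the others 10, and 8 of the 35 splits gave at least 6. The split with 10 put siECHS1 replicate 1 with siNC replicates 1, 2 and 4, which keeps part of the group difference. Most others that reached 6 were of this kind, but a split with 2 libraries of each group on either side gave 8. The splits are thus not a clean reference, and chance cannot be excluded for the number of lists called at the preset correlation.

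Collagen, decorin and periostin transcripts rose while 5 cardiomyocyte markers fell. A larger share of fibroblasts in the siECHS1 cultures would raise the fibroblast markers alike, but of 9 markers 4 rose and 1 fell. These calls argue against it as the whole cause. Cochran's Q over the 9 markers was 308.6 (exact permutation p = 0.0286, the smallest that 35 splits allow). A smaller share of cardiomyocytes would raise the markers of all other cell types alike, and 31 of these moved apart as well (Q 653.8, exact permutation p = 0.0286, with 6 up and 4 down). The calls in both directions were known before Q was chosen, and splits that mix the groups shrink every change. The p-values of Q therefore restate the calls and are no separate evidence. Low markers shift less on the log2(FPKM + 1) scale, and a smaller change of share beside other changes is not excluded. A hypothesis left open is a change of matrix genes within the cells that make them.

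More genes fell than rose. Scaling between libraries is a candidate explanation: under the 3 other scalings the share that rose lay between 45.9% and 50.9%, against 42.0% as deposited, and the bounds for this test were set after the values were seen. With a length trend removed, 41.8% of 3003 changed genes rose when each library's mean was kept, and 48.2% of 2812 when it was not, which also rescales the libraries. The bounds asked both runs to agree, so the test as worded gave no verdict. The run that kept the means removes the length trend alone, and it left the share near the 42.0% as deposited. Over the tested genes log2 fold change and length had a Spearman correlation of -0.00044. These values argue against gene length as the cause of the excess of falls. A biological excess of falls in siECHS1 stays open and untested.

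Interferon-related transcripts moved in both directions, with Oasl, Ifit3 and Cxcl10 up and Stat2 and Usp18 down. A smaller share of leukocytes would lower their markers alike, but 5 markers moved apart (Q 88.6, exact permutation p = 0.0286, Cd68 up and Csf1r down). Here too the calls were known before Q was chosen, so its p is no separate evidence. Only 5 of the 10 listed markers were tested, and 1 rose and 1 fell past the threshold. A smaller share of leukocytes beside other changes is therefore not excluded. By limma 3 of 24 genes of the list rose and 12 fell. Whether the 15 changes follow from the sequence of the RNA duplex or from the lower level of Echs1 cannot be told apart, because the design holds 1 treated and 1 control group.

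A hypothesis fixed before its test was that ATF4 targets and endoplasmic reticulum chaperones shared a common change across libraries. The test took the whole unfolded protein and heat shock list for the chaperones, so heat shock genes such as Dnajb1 and Hsph1 were included. Over the 8 libraries, the deviations of the mean levels of both lists from their group means had a Pearson r of 0.237 (exact permutation within groups, two-sided p = 0.674) and a Spearman rho of 0.19 (exact permutation p = 0.722). Without the 2 libraries farthest from the median r was -0.477. This was the 1 relation of its kind computed, and it neither showed nor excluded a link between the lists. The endoplasmic reticulum chaperones alone were not tested.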
